A study of Homo sapiens with 4 samples.

How the data were processed

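The series holds 4 libraries of the human embryonic stem cell line H1, taken at days 0, 2, 4 and 6 of hematopoietic differentiation in culture, with 1 library per day. Per the labels, cells were captured on a 10x Genomics Chromium instrument with a 3' kit and sequenced on an Illumina HiSeq X. Per the submitters' processing notes, reads were processed with Cell Ranger 3.1.0 against GRCh38. The notes name no gene annotation, barcode filter or later step. The deposited day 6 values are raw UMI counts per gene and cell barcode, per the file headers and the whole-number values, with no normalization by the authors on record. For days 0, 2 and 4 the barcode and gene lists were used; their counts were not used here, so these 3 libraries entered no expression comparison. Of the 33538 gene identifiers, 33456 were found in GENCODE 29, and the symbol was equal for 33071.

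Before the data were examined, the filters, clustering settings, marker lists, gene lists, rule for named genes and most alternatives were fixed. Barcodes were kept with at least 500 genes and at most 10% mitochondrial UMIs. Of 5379 barcodes, 697 had fewer genes, 705 had more mitochondrial UMIs and 900 were removed for either reason. Scrublet, as carried in scanpy 1.11.5, marked 53 of the remaining 4479 (1.18%, threshold 0.331) as doublets. These were left out, which gave 4426 cells with 131772479 UMIs. MALAT1, the most abundant gene, took 1.99% of the UMIs. Counts were scaled to 10000 per cell and log-transformed, and 2000 variable genes were chosen. The readout panel of 3023 genes, which holds the members of the gene lists and their families, and mitochondrial and ribosomal protein genes were kept out of this choice, so that the reported genes did not define the clusters. Values were scaled with a limit of 10, reduced to 30 principal components, joined to 15 neighbours and clustered by the Leiden method at resolution 1 with a fixed seed, which gave 15 clusters. Endothelial-like cells were clustered again at resolution 0.6 into 6 sub-clusters. The software was Python 3.11.15 with anndata 0.12.19, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, python-igraph 0.11.9 and matplotlib 3.10.9.

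Clusters were named after the data were seen, from 17 fixed marker lists and each cluster's 10 leading genes. Where cell cycle or other genes led a cluster, the levels of the fixed markers decided. Cluster 2, led by KRT19, was counted as mesenchymal-like in a first version and was then left unnamed, because its leading markers belonged to epithelial and cardiac lists; the earlier choice is kept as an alternative. Blood-like cells joined the progenitor-like and erythroid-like clusters. Cluster 14, counted as erythroid-like, held 112 barcodes of low depth (median 4730.5 UMIs), of which 93 had at most 0.5% mitochondrial UMIs. Endothelial sub-cluster 4, of 139 cells, was led by the matrix and muscle genes COL1A1 and DES and stayed in the endothelial-like class. Other steps chosen after the data were seen were the second clustering of blood-like cells at resolution 0.6 into 7 sub-clusters, the comparison of blood sub-cluster 5 with arterial-like cells, that of smooth muscle-like with mesenchymal-like cells, and the pooling of these 2 classes as a reference for low-UMI barcodes.

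For each comparison, UMIs were summed over the cells of a set and expressed as counts per 1000000 (CPM). Log2 ratios used a pseudocount of 10 CPM, while printed folds are plain ratios of CPM with an exact conditional binomial 95% interval. Levels carry exact Poisson intervals and shares exact Clopper-Pearson intervals. All cover counting error only. A gene counted as higher or lower when the ratio after the pseudocount reached 2-fold, which is a rule of size and not a test. Each of 20 gene lists was summarised by the median over members with at least 20 CPM in either set, and set against 10000 random lists of the same number of genes matched on expression. A list was called apart when it lay in the outer 2.5% on either side. Random genes were drawn independently of each other, so lists of genes that vary together can lie apart more often than this share. With 1 library there were no replicates, so no p-values were computed. Named genes were the 10 highest and 10 lowest panel genes with at least 50 CPM in the higher set, and up to 3 members of each list in the direction of its median and 1 against it. Of these the text gives a part, and RUNX1 always. For detection shares, each cell was thinned at random to 5000 UMIs. The rule for the main value of each comparison (the highest and lowest median among lists that were apart and had at least 5 measured members) was set after the medians were seen.

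The ratio and clustering steps were tested on simulated data, after the main run. For arterial-like against other endothelial-like cells, 5105 genes were drawn with 200 changed. The intervals covered 96% of the changed ratios, 100% of 4-fold changes passed 2-fold, 0 unchanged genes did, and 8 of 100 unchanged lists lay in the outer 5%. For blood-like against endothelial-like cells, over 5046 genes, these values were 92.5%, 98%, 0 and 7 of 100. The clustering placed 97.9% of 1000 simulated cells of 4 classes with their own class, in a simulation without variation inside a class. These simulations took their means from the real classes.

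The alternatives changed the mitochondrial limit to 5%, the gene minimum to 1500, the use of doublet calls, the resolution to 0.5 or 2, the number of variable genes to 4000, the panel exclusion, the UMIs used for clustering against those used for values, the scaling to median-of-ratios, the pseudocount to 1 CPM, the summing to a mean over cells, the expression minimum for list members, the thinning to 2500 UMIs and the detection minimum to 2 UMIs. Alternatives added after the data were seen concern single clusters or sub-clusters, barcodes with at most 0.5% mitochondrial UMIs, and the expected RUNX1 share over all draws. Where cells were clustered again, each new cluster took the class that most of its cells had in the main run. No new cluster was named from its own markers.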

Results

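The series followed H1, an established human embryonic stem cell line, through hematopoietic differentiation in culture. A droplet-based single-cell RNA library was made at each of days 0, 2, 4 and 6, so each day had 1 library and there were no replicates. The deposited barcode lists held 11934 barcodes at day 0, 37586 at day 2, 9122 at day 4 and 5379 at day 6, and all 4 libraries listed the same 33538 genes. The labels name about 5000 cells and do not state how the lists were filtered, so the day 2 list in particular is not a count of cells. Expression counts were analysed for day 6 only; those of days 0, 2 and 4 were not analysed here. The day 6 library held 135996993 unique molecular identifiers (UMIs, counts of single captured transcripts) in which 23463 genes were detected. Its barcodes ranged from 501 to 106260 UMIs, with a median of 25833 UMIs and 4830 genes. After filtering, 4426 barcodes remained as cells, with a median of 28998.5 UMIs and 5062 genes. Every comparison was made between sets of cells inside this single library, so no significance test was possible, and all intervals are 95% intervals that cover counting error only.

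The first question was which cell types the day 6 culture held. Endothelial-like cells, the cells that line vessels, made up 1584 of 4426 cells (35.8%, exact Clopper-Pearson interval 34.4 to 37.2%). Mesenchymal-like cells made up 32.4% (1432 cells, 31.0 to 33.8%), and smooth muscle-like cells 9.11% (403 cells, 8.27 to 9.99%). Blood-like cells made up 11.5% (511 cells, 10.6 to 12.5%). Of these, 182 were progenitor-like (4.11%, 3.55 to 4.74%) and 329 erythroid-like (7.43%, 6.68 to 8.25%). The erythroid-like class was not uniform. All 116 cells of a blood sub-cluster led by the megakaryocyte markers PF4 and PLEK fell in it, with PF4 at 422 CPM and HBG2 at 3451 CPM, against 56.3 and 6073 CPM in the other blood-like cells. It also includes 112 barcodes of low depth (cluster 14). In these, the nuclear RNAs MALAT1 and NEAT1 had log2 ratios of −2.62 and −2.97 against the other erythroid-like cluster. The median of 3 other nuclear noncoding RNAs was −0.16, with KCNQ1OT1 at −2.52, JPX at −0.16 and PVT1 at 0.13. Whether all of these barcodes are whole cells stays open. Within the endothelial-like class, 508 of 1584 cells formed the arterial-like sub-cluster (32.1%, 29.8 to 34.4%). The classes were named from marker genes, which define them and are not results. The endothelial-like class carried CDH5, the cadherin of endothelial junctions, at 183 CPM (UMIs of a gene per 1000000 UMIs summed over the class). LUM, a matrix proteoglycan, reached 1498 CPM in the mesenchymal-like class, and TAGLN, an actin-binding muscle protein, 2485 CPM in the smooth muscle-like class. RUNX1, the transcription factor needed for blood cell emergence, stood at 108 CPM in the progenitor-like class, and the fetal globin gene HBG2 at 8331 CPM in the erythroid-like class. The copies HBG1 and HBG2 are nearly identical in sequence, so the split of UMIs between them is uncertain. A cluster of 300 cells led by the keratin gene KRT19 (1705 CPM) stayed unnamed (6.78%, 6.05 to 7.56%). It carried the mesenchymal marker LUM and the cardiac marker HAND1 as well. Another unnamed cluster held 196 barcodes (4.43%, 3.84 to 5.08%), with a median of only 1543.5 UMIs and 0.0774% mitochondrial UMIs. None of the fixed pluripotent, lymphoid, myeloid or mast cell markers was among the 10 leading genes of any cluster. Genes outside these fixed lists, such as TREM2 and CSF3R among the leading genes of blood sub-cluster 3, were not counted. Mesenchymal-like cells outnumbered endothelial-like cells with doublet calls kept in (34.8% against 33.5%), with at most 5% mitochondrial UMIs (37.1% against 34.8%) and with 4000 variable genes (35.5% against 34.9%). The smooth muscle-like share was 14.9% at resolution 0.5, where no cluster consisted mainly of the KRT19-led cells. The KRT19-led share was 3.68% with at most 5% mitochondrial UMIs, and that of the low-UMI cluster 1.05% with at least 1500 genes per barcode.

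**Figure D1:**
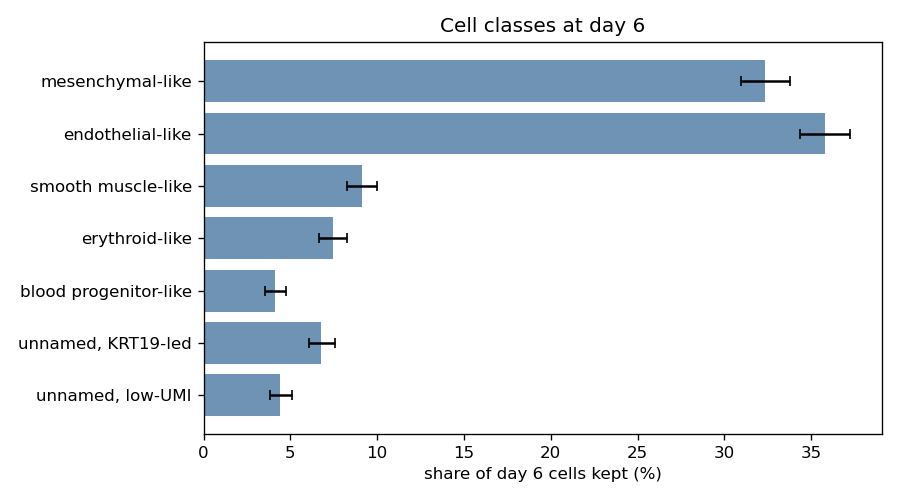
Share of the 4426 day 6 cells in each cell class, in percent, as bars with exact 95% Clopper-Pearson intervals. Endothelial-like cells made up 35.8% and mesenchymal-like cells 32.4%, and blood-like cells made up 11.5%.

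Arterial-like cells were compared with the other endothelial-like cells, because the series title places arterial endothelium at the centre of T cell production from pluripotent stem cells. The arterial-like cells held more transcripts of single genes of the Notch and VEGF pathways and of vascular basement membrane (2 of 7, 1 of 7 and 3 of 19 measured list members passed 2-fold), and fewer transcripts of most G2 and M phase genes. HES4, a transcriptional repressor of the Notch target family, stood at 326 CPM against 73.2 CPM, a 4.45-fold difference (exact conditional binomial interval 4.21 to 4.70). NOTCH4, the Notch receptor typical of endothelium, was 2.98-fold higher (2.74 to 3.24). ESM1, a proteoglycan secreted by sprouting endothelium, was 3.65-fold higher (3.47 to 3.85), and COL4A1, a basement membrane collagen, 2.51-fold higher (2.43 to 2.59). CENPF, a kinetochore protein of dividing cells, was 23.9-fold lower (17.5 to 33.6), at 3.82 CPM against 91.3 CPM. The comparator included a sub-cluster of cycling cells, taken up below.

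The Notch list had 7 measured members (at least 20 CPM in either set), with a median log2 ratio of 0.67, above 99.99% of random lists of matched expression. Of these, 2 were at least 2-fold higher after the pseudocount, HES4 and NOTCH4, and none was lower. The fixed arterial markers include the Notch pathway genes DLL4, HEY1 and HEY2, so this contrast may follow in part from how the set was named. The ligand gene JAG2 stood at 39.5 against 16.0 CPM and HES1, the opposite case, at 47.1 against 71.7 CPM. The VEGF and angiopoietin list had a median of 0.65 over 7 members. ESM1 was the only one of these to pass 2-fold after the pseudocount, and the co-receptor NRP1 (105 against 51.4 CPM) and the receptor FLT4 (24.1 against 10.96 CPM) did not reach that bound. The BMP and TGF-beta list had a median of 0.39 over 11 members, led by the co-receptor ENG at 513 against 212 CPM. SMAD6 (171 against 89.3 CPM) and ACVRL1 (142 against 79.0 CPM) followed, while TGFBI was 2.57-fold lower. Basement membrane and matrix genes had a median of 0.17 over 19 members, with 3 higher and 1 lower. COL4A1, LAMA4 (4.85-fold) and HSPG2 (2.44-fold) were higher, and FN1, fibronectin, was 4.13-fold lower at 50.9 against 210.2 CPM. FN1 is among the leading genes of endothelial sub-cluster 4, which also carried COL1A1 in 136 of its 139 cells. Without that sub-cluster the log2 ratio of FN1 was −1.41 in place of −1.85. COL1A1 was also found in 37.2 to 66.2% of cells of the other comparator sub-clusters, against 21.5% of arterial-like cells. The blood stem cell programme had a median of 0.21 over 12 members. Its surface marker CD34 stood at 592 against 333 CPM, and HOPX at 350.5 against 218 CPM. The interferon and inflammatory list (median 0.31, 1 of 14 members higher) was led by HLA-B at 46.7 against 15.4 CPM, and the HOXB cluster (0.31, 0 of 6 higher) by HOXB6 at 87.6 against 55.4 CPM. HOXB2 went the other way, at 17.6 against 32.7 CPM.

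Genes of cell division were lower in the arterial-like cells. The G2 and M phase list had a median of −1.53, with 28 of 34 measured members at least 2-fold lower and none higher. The S phase list had a median of −0.82, with 9 of 22 lower. UBE2C, the ubiquitin carrier that ends mitosis, was 10.2-fold lower, the spindle factor TPX2 13.9-fold and the proliferation antigen MKI67 15.7-fold. In S phase, the replication factor GINS2 was 6.29-fold lower and TYMS, thymidylate synthase, 3.60-fold. The comparator included a cycling sub-cluster of 258 cells. Dividing cells of arterial type may have been placed in it, so the contrast follows in part from how the sets were drawn. Without it the G2 and M median was −0.20 and the S phase median −0.25. Against the venous-marker sub-cluster alone they were −0.43 and −0.39. The comparator also moved the blood stem cell median, to 0.14 without the cycling sub-cluster, and the BMP and TGF-beta median, to 0.26 against the venous-marker sub-cluster. Among single genes outside these lists' leaders, COL15A1, a collagen of vessel walls, was 6.57-fold higher, CD300LG 5.45-fold, IL3RA, the interleukin 3 receptor chain, 4.06-fold, CYP1A1 3.27-fold and the endothelial transcription factor SOX18 2.44-fold. IGFBP7 was 7.35-fold lower. Of 16 lists with at least 5 measured members, 7 lay above and 2 below the central 95% of random lists. The other 7 lay within it: cytokine receptors (0.06), integrins (−0.06), glycolysis (−0.01), oxidative phosphorylation (0.03), cholesterol synthesis (0.07), haem synthesis (0.03) and heat shock (−0.11). Lists with fewer members were WNT (0.24), retinoic acid (0.21, with a mean of −0.15) and lymphoid transcription (0.05). No HOXA gene reached 20 CPM in any set. With members under 20 CPM in both sets kept, the median was 0.09 for the Notch list, 0.07 for the VEGF list, 0.18 for the BMP and TGF-beta list, 0.19 for the HOXB cluster, 0.084 for the matrix list and 0 for the interferon list. The matrix median was 0.38 with at least 1500 genes per barcode and 0.29 with doublet calls kept in.

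**Figure D2:**
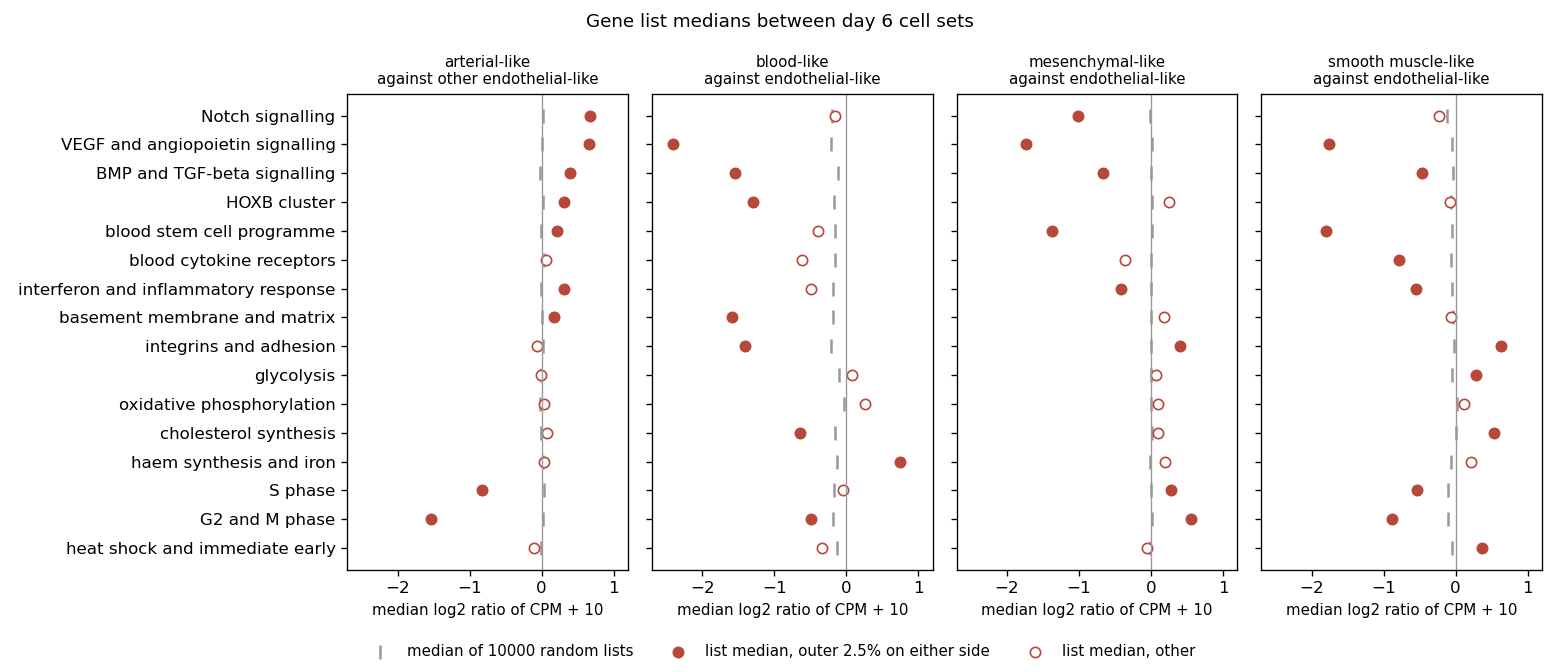
Median log2 ratio of CPM for each readout list in the comparisons of day 6 cell sets; filled points lie in the outer 2.5% of 10000 expression-matched random lists on either side, and grey ticks mark the median of the random lists. The lowest median for arterial-like against other endothelial-like cells was that of G2 and M phase (−1.53), and for blood-like against endothelial-like cells that of VEGF and angiopoietin signalling (−2.41).

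Blood-like cells were compared with endothelial-like cells to describe what sets the blood lineage apart, since the labels call the cultures hematopoietic from day 2. Blood-like cells held fewer transcripts for VEGF reception, BMP response, matrix and adhesion, and more for haem synthesis and iron handling. ESM1 was 93.1-fold lower (62.5 to 145), at 1.64 against 153 CPM, and KDR, the main VEGF receptor, 6.91-fold lower (6.37 to 7.51). ID1, a direct BMP target, was 9.77-fold lower (9.46 to 10.1), at 263 against 2569 CPM. GATA1, the master transcription factor of red cells and platelets, stood at 172 against 0.679 CPM, 253-fold higher (172 to 388). SLC25A37, the iron importer of mitochondria, was 6.11-fold higher (5.67 to 6.58).

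The VEGF and angiopoietin list had a median log2 ratio of −2.41. Of its 7 measured members, 6 were at least 2-fold lower, among them the protease ADAMTS1 (3.76 against 73.8 CPM). ANGPT1, a ligand of the TIE2 receptor, was the exception, at 21.03 against 3.78 CPM. The BMP and TGF-beta list had a median of −1.55 with 7 of 11 lower, including ENG (25.5 against 294 CPM) and ID3 (193 against 1583 CPM). Matrix genes had a median of −1.58 with 14 of 17 lower. COL4A1 was 18.0-fold lower, COL4A2 10.6-fold and COL5A2 20.6-fold. Integrins and adhesion genes had a median of −1.40 with 7 of 10 lower, including CD9 (18.6-fold), ITGB1 (3.73-fold) and ITGA5 (4.12-fold). The HOXB cluster had a median of −1.30 with 3 of 5 lower, led by HOXB7 at 7.03 against 38.3 CPM. Cholesterol synthesis had a median of −0.65 with 4 of 14 lower, among them the enzymes SC5D (4.11-fold), MSMO1 (2.88-fold) and FDPS (2.19-fold). Haem synthesis and iron genes had a median of 0.75 with 4 of 10 higher and none lower. BLVRB stood at 277 against 63.1 CPM and the haem enzyme CPOX at 56.3 against 14.5 CPM. The G2 and M list had a median of −0.49, with 1 of 30 members lower (BIRC5) and 1 higher (CKS2).

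The blood stem cell programme split in the blood-like cells. GATA2 was 4.52-fold higher at 128 against 28.2 CPM, while HOPX was 5.25-fold lower, HMGA2 6.20-fold and PROCR 4.38-fold. The list's median was −0.40, with 5 of 13 lower and 1 higher, and lay within the range of random lists. The highest single ratios also included IGFBP5 at 316 against 5.53 CPM, TIMP3, an inhibitor of matrix proteases, at 612 against 82.2 CPM, the tetraspanin CD82 (11.3-fold), the chemokine CXCL3 (42.0-fold) and LMO4 (5.54-fold). TIMP3 and CXCL3 were among the leading genes of the PF4-led sub-cluster (1127 and 120 CPM), and without it stood at 389 and 32.5 CPM in blood-like cells. RUNX1, a marker that helped define the class, was 65.1-fold higher (49.3 to 87.6). Among lists within the random range, oxidative phosphorylation stood at 0.25, glycolysis at 0.08, S phase at −0.05, Notch at −0.16, interferon at −0.50, cytokine receptors at −0.62 and heat shock at −0.33. The median of all genes in this comparison was −0.14. With median-of-ratios scaling, the VEGF median was −2.30 and the haem median 0.89. With every cell weighted alike the G2 and M median was −0.12, and with members under 20 CPM kept medians were −0.60 for VEGF, −0.62 for BMP and TGF-beta, −0.65 for HOXB and −0.39 for integrins.

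RUNX1 in endothelial-like cells was examined because the gene marks hemogenic endothelium, the vessel cells that give rise to blood. RUNX1 was rare in the endothelial-like class, at 1.36 CPM against 88.4 CPM in blood-like cells. Because RUNX1 was among the markers that named the blood-like cells, this contrast follows in part from how the classes were drawn. Cells with both RUNX1 and endothelial genes, such as blood sub-cluster 5 described below, were counted as blood-like. In the endothelial-like class RUNX1 was 2.23-fold higher than in mesenchymal-like cells (0.609 CPM, 1.39 to 3.62). It was 2.10-fold higher than in smooth muscle-like cells (0.647 CPM, 1.08 to 4.46). Within the class, arterial-like cells held RUNX1 at 2.28 times the level of the other endothelial-like cells (2.29 against 1.01 CPM, 1.26 to 4.07). The globin gene HBG2 of the erythroid-like cells moved in the same way, at 2.84 times the level in arterial-like cells (48.1 against 16.9 CPM), and at 25.4 CPM in endothelial-like against 13.4 CPM in mesenchymal-like and 7.24 CPM in smooth muscle-like cells. SPI1, a blood transcription factor, was 3.50-fold higher in endothelial-like than in mesenchymal-like cells (1.28 against 0.366 CPM). Free blood RNA and expression by endothelial cells were therefore not separated. By cells, 47 of 1584 endothelial-like cells held a RUNX1 UMI (2.97%, 2.19 to 3.93%), 29 of 1432 mesenchymal-like cells (2.03%, 1.36 to 2.90%) and 11 of 403 smooth muscle-like cells (2.73%, 1.37 to 4.83%). The median depths of these classes were 23087.5, 33042.5 and 41948 UMIs. In the planned single random draw of 5000 UMIs per cell, RUNX1 was found in 0.448% of endothelial-like cells (7 of 1564, 0.180 to 0.920%), 0.702% of mesenchymal-like cells (10 of 1424, 0.337 to 1.29%) and 0.503% of smooth muscle-like cells (2 of 398, 0.0609 to 1.80%). Over all possible draws, a calculation added after that draw was seen, the expected shares were 0.742%, 0.301% and 0.347%, so the order of the classes in the single draw did not hold over all draws. With at least 1500 genes per barcode the expected endothelial-like share was 0.889%, and with doublet calls kept in 0.776%. Inside the class, RUNX1 was found in 4 of 499 arterial-like and 3 of 1065 other endothelial-like cells in the draw of 5000 UMIs, and in 2 of 503 and 6 of 1069 in a separate draw of 2500 UMIs. The expected share at 5000 UMIs was 1.18% in arterial-like cells. Before thinning, a RUNX1 UMI was found in 21 of 508 arterial-like cells (4.13%). Endothelial sub-cluster 5, which belongs to the comparator, was close to this with 6 of 156 cells (3.85%). The higher share was thus not particular to arterial-like cells. Blood-like cells reached 35.3% in the draw (159 of 450, 30.9 to 39.9%).

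Clustering the blood-like cells again, a step chosen after the data were seen, separated a group of 54 cells in which RUNX1 occurred beside endothelial genes. This blood sub-cluster 5 held RUNX1 at 102 CPM (85.6 to 121), against 2.29 CPM in arterial-like cells and 107 CPM in a progenitor sub-cluster of 70 cells with lower levels of the endothelial genes. Its level of CDH5 was 134 CPM, against 261 CPM in arterial-like cells and 47.4 CPM in the progenitor sub-cluster. RAMP2, a receptor partner abundant in endothelium, stood at 362 against 40.4 CPM in the progenitor sub-cluster, the fenestra protein PLVAP at 461 against 253 CPM and PECAM1 at 139 against 118 CPM. In 44 of the 54 cells (81.5%) at least 1 UMI of both RUNX1 and CDH5 was found. The same held for 49 of 70 cells of the progenitor sub-cluster, 36 of 55 of cycling blood sub-cluster 0, 21 of 508 arterial-like and 4 of 1432 mesenchymal-like cells, so joint detection was not particular to this group. These markers led to the group and are not results of it. The genes kept out of the clustering differed as follows. Against arterial-like cells, ESM1 was 86.8-fold lower (37.2 to 267), COL4A1 7.35-fold, ENG 6.15-fold and NOTCH4 7.46-fold. IGFBP5 was 46.5-fold higher (30.3 to 74.1), CD82 15.2-fold, the junction protein CLDN10 17.1-fold, the mitochondrial chaperone HSPD1 2.25-fold, and MFNG, a modifier of Notch receptors, 2.10-fold. The matrix list had a median of −1.18 with 11 of 18 members lower, and cholesterol synthesis −1.11 with 9 of 14 lower. Medians were also lower for VEGF (−1.48), BMP and TGF-beta (−1.20), integrins (−0.73), interferon (−0.67), Notch (−0.62) and heat shock (−0.61), and higher for S phase (0.36). With 4000 variable genes, the cholesterol median was −0.48, the heat shock median −0.17 and the S phase median 0.77. With every cell weighted alike, the Notch median was −0.24, the interferon median −0.40 and the S phase median 0.96, and with members under 20 CPM kept, medians were −0.046 for Notch, −0.22 for interferon, −0.56 for VEGF, −0.61 for BMP and TGF-beta, −0.41 for integrins and −0.038 for heat shock.

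**Figure D3:**
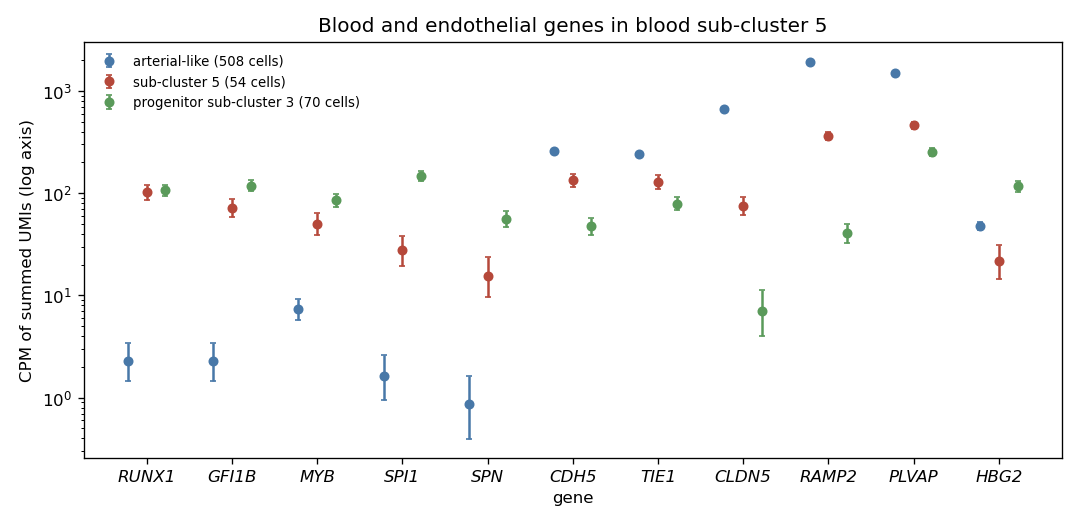
CPM of marker genes, on a log axis, in arterial-like cells (508 cells), blood sub-cluster 5 (54 cells) and progenitor sub-cluster 3 (70 cells), with exact 95% Poisson intervals as bars. RUNX1 in sub-cluster 5 (102 CPM) was near that of sub-cluster 3 (107 CPM), and its CDH5 level (134 CPM) lay between those of sub-cluster 3 (47.4 CPM) and arterial-like cells (261 CPM).

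Mesenchymal-like cells were compared with endothelial-like cells as the largest non-vascular class. They held fewer transcripts of many VEGF pathway, Notch and blood stem cell programme genes. CD34 was 45.3-fold lower (41.2 to 49.9), at 8.92 against 404 CPM, and ESM1 123-fold lower (95.7 to 161). IGFBP3 was 37.4-fold higher (32.7 to 43.0), at 210 against 5.61 CPM. HOXC8, a gene of trunk position, stood at 95.8 against 1.33 CPM, and CRABP2, a carrier of retinoic acid, at 228 against 27.3 CPM. The VEGF list had a median of −1.73 with 5 of 8 members lower, among them KDR (8.56-fold) and FLT1 (4.17-fold), and 2 higher, including the ligand PGF at 94.4 against 11.4 CPM. The blood stem cell programme had a median of −1.37 with 8 of 13 lower, including LMO2 (16.5-fold) and LYL1 (6.85-fold), while MLLT3 was 5.92-fold higher. The Notch list had a median of −1.02 with 4 of 8 lower, led by NOTCH4 (34.1-fold) and MFNG (68.0-fold). The BMP and TGF-beta list (−0.67) split, with 4 of 13 lower and 2 higher; ENG was 8.90-fold lower and TGFBI 7.47-fold higher. Interferon genes had a median of −0.41, led by HLA-E at 49.0 against 323 CPM. Integrins and adhesion genes had a median of 0.40 with 2 of 11 higher, CDH11 (9.76-fold) and ITGAV (3.05-fold), and 1 lower, ITGA9 (3.82 against 28.8 CPM). COL6A3, a collagen of connective tissue, was 14.98-fold higher, VCAN 4.58-fold and the glucose carrier SLC2A1 8.19-fold. The G2 and M median was 0.56 and the S phase median 0.27, although none of the 37 and 22 members passed 2-fold. Counting the KRT19-led cluster as mesenchymal-like, the S phase median was 0.05, and it was 0.02 when clusters and values came from separate UMIs. With members under 20 CPM kept, medians were −0.58 for VEGF, 0.01 for Notch, 0.00479 for integrins, 0 for interferon genes, −0.14 for BMP and TGF-beta and −0.61 for the blood stem cell programme.

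Smooth muscle-like cells were compared with endothelial-like cells in the same way. CD34 was 99.5-fold lower (78.6 to 128) and KDR 22.1-fold lower (19.3 to 25.3), while TNFRSF12A, a receptor of the tumour necrosis factor family, was 25.7-fold higher (23.0 to 28.7), at 240 against 9.34 CPM. IGFBP7 stood at 669 against 64.8 CPM, CRABP2 at 311 against 27.3 CPM and TGFBI at 387 against 45.3 CPM. The blood stem cell programme had a median of −1.80 with 8 of 12 lower, including LMO2 (30.7-fold) and LYL1 (12.8-fold), and HMGA2 was 2.24-fold higher. The VEGF list had a median of −1.76 with 6 of 8 lower and 2 higher. Integrins and adhesion genes had a median of 0.63 with 5 of 11 higher, led by CDH11 (14.04-fold), ITGAV (4.96-fold) and ITGA1 (3.63-fold), and with ITGA9 12.9-fold lower. Cholesterol synthesis had a median of 0.54, led by MVD at 228 against 104 CPM. Glycolysis had a median of 0.28, led by SLC2A1 (10.7-fold), and heat shock genes 0.37, led by the chaperone gene HSPA5 (481 against 181 CPM). The heat shock median was −0.02 when clusters and values came from separate UMIs. Cell cycle genes were lower, with medians of −0.89 for G2 and M (12 of 30 lower) and −0.54 for S phase (4 of 19 lower). HMGB2 was 5.16-fold lower and UBE2C 5.80-fold. The endothelial-like class includes a cluster of 280 cells with MKI67 among its leading genes, while the smooth muscle-like class is 1 cluster. How much of this difference follows from how the classes were drawn was not tested. Medians were also lower for cytokine receptors (−0.79, 1 of 6 lower), interferon genes (−0.55, 3 of 15 lower) and the BMP and TGF-beta list (−0.46, 5 of 12 lower and 3 higher). With members under 20 CPM kept they were −0.075, −0.31 and −0.16. In the same setting medians were −0.56 for VEGF, −0.9955 for the blood stem cell programme, 0.067 for integrins, 0.11 for glycolysis and 0.16 for heat shock. The BMP and TGF-beta median was −0.22 with doublet calls kept in, that of cytokine receptors −0.52 at resolution 0.5, and that of S phase −0.35 with every cell weighted alike. IL3RA was 100.2-fold lower and IFI16 9.82-fold, while the chemokine gene CCL2 stood at 25.96 against 0.914 CPM.

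Positions of the genes that lead these comparisons are those of GENCODE 29 on the GRCh38 build, matched by gene identifier. HES4 (ENSG00000188290) lies on chromosome 1 from 998962 to 1000172, CD34 (ENSG00000174059) on chromosome 1 from 207880972 to 207911402, and ESM1 (ENSG00000164283) on chromosome 5 from 54977864 to 55022671. NOTCH4 (ENSG00000204301) lies on chromosome 6 from 32194843 to 32224067, COL4A1 (ENSG00000187498) on chromosome 13 from 110148963 to 110307233, and ID1 (ENSG00000125968) on chromosome 20 from 31605283 to 31606515. RUNX1 (ENSG00000159216) lies on chromosome 21 from 34787801 to 36004667, GATA1 (ENSG00000102145) on chromosome X from 48786554 to 48794311, and TNFRSF12A (ENSG00000006327) on chromosome 16 from 3018445 to 3022383.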

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

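Of the 3 tests in this part, the test for nuclei was chosen only after the level of MALAT1 had been seen, and the demand that a whole counting interval pass the stated bound was added after all 3 values were seen.

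A cluster of 196 barcodes drew attention because it enters no comparison, with a median of 1543.5 UMIs and 0.0774% mitochondrial UMIs. Against mesenchymal-like and smooth muscle-like cells, MALAT1, an RNA held in the nucleus, had a log2 ratio of −2.748 (−2.81 to −2.67), which argues against nuclei stripped of cytoplasm. The basement membrane and matrix list, whose transcripts are translated on the endoplasmic reticulum, had a median of −2.37 (−2.56 to −2.09) with 18 of 18 members lower, while cytosolic enzymes and cytoskeleton genes had 0.51. These barcodes may therefore be pieces of cytosol that lack endoplasmic reticulum and mitochondria. Their cell type of origin is not known, however, so the reference classes may not be their source. Between named classes the same list was also low, at −1.58 in blood-like against endothelial-like cells with 14 of 17 members lower. The test thus could not tell a loss of endoplasmic reticulum from a cell type with little matrix expression. Whether these barcodes also lack a nucleus stays open, because the 3 other nuclear noncoding RNAs, KCNQ1OT1, FTX and JPX, did not move alike. Their median was −1.028 (−1.67 to −0.54), with KCNQ1OT1 at −3.27 and JPX at only −0.37. NEAT1, another nuclear RNA, had −3.17 (−3.76 to −2.63).

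Another 536 barcodes had over 50% mitochondrial UMIs, with a median of 1324 UMIs, and stood apart as a signal in barcodes that no comparison used.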

How the results depend on the processing

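The alternatives that concern single clusters or sub-clusters, barcodes with at most 0.5% mitochondrial UMIs, the second clustering of blood-like cells and the expected RUNX1 share were chosen only after the data were seen. No paired analysis was possible because there was 1 library per day. Of 1260 values of list medians under the alternatives, 17 were counted as a change of sign, and of 5852 values of single genes, 13 were. Sign changes of very small reported log2 ratios were left out of both counts. Of the same values of list medians, 352 moved beyond their counting interval without a counted change of sign. Of these, 313 belonged to medians other than the main values of the comparisons, and the text prints only a part of them. Unless the alternative's own construction shows it, the cause was not tested. Depth limits how often a rare transcript such as RUNX1 is found, and the shares of the smaller classes depend on the clustering.

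With doublet calls kept in, shares were 33.49% endothelial-like, 34.76% mesenchymal-like, 6.988% smooth muscle-like and 8.439% KRT19-led, the arterial-like share was 41.0%, RUNX1 was found in 0.9428% of endothelial-like cells, and the G2 and M median in arterial-like cells was −1.606. The retinoic acid median turned to −0.06476 in mesenchymal-like and −0.4362 in smooth muscle-like cells. Without barcodes of at most 0.5% mitochondrial UMIs, shares were 38.53% endothelial-like, 34.78% mesenchymal-like, 9.812% blood-like and 0.5437% for the low-UMI cluster, which that filter removes by construction. With at most 5% mitochondrial UMIs, shares were 37.11% mesenchymal-like, 10.1% smooth muscle-like, 9.351% blood-like and 3.681% KRT19-led. The haem median of blood-like cells was then 0.7096, the G2 and M median of mesenchymal-like cells 0.4797, and the retinoic acid median of smooth muscle-like cells turned to −0.01753.

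With at least 1500 genes, shares were 34.12% mesenchymal-like, 11.14% smooth muscle-like, 1.051% for the low-UMI cluster and 29.6% arterial-like, and RUNX1 was found in 1.19% of endothelial-like cells. Medians were 0.5693 for Notch and −1.617 for G2 and M in arterial-like cells, 0.4125 for G2 and M in mesenchymal-like cells and −1.725 for the blood stem cell programme in smooth muscle-like cells. The retinoic acid median turned to −0.07764 in mesenchymal-like and −0.3986 in smooth muscle-like cells, and CCNB2 in blood sub-cluster 5 turned to 0.01911. With 4000 variable genes, shares were 35.47% mesenchymal-like, 7.162% smooth muscle-like, 5.49% low-UMI, 5.671% KRT19-led and 22.01% arterial-like. Medians were 0.5096 for Notch and −1.625 for G2 and M in arterial-like cells and 0.3984 for G2 and M in mesenchymal-like cells. In arterial-like cells IDI1 (−0.1144), MSMO1 (−0.2019) and RXRA (−0.0258) turned, and in blood sub-cluster 5 BIRC5 (0.5598), CCNB2 (0.2625) and TUBB4B (0.2272).

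With clusters and values from separate random parts of the UMIs, shares were 35.36% mesenchymal-like, 12.38% smooth muscle-like, 5.151% low-UMI, 0% KRT19-led and 28.01% arterial-like. The class names in this setting were carried over from the main clusters, which used all UMIs, so names and values were not fully separate. The G2 and M median of mesenchymal-like cells was 0.3903 and the integrin median of smooth muscle-like cells 0.5325, and in the latter the heat shock median (−0.01826) and SFRP1 (0.651) turned. At resolution 0.5, shares were 14.87% smooth muscle-like, 0% KRT19-led and 37.95% arterial-like. At resolution 2, the smooth muscle-like share was 7.817% and its integrin median 0.569. With all genes open to the clustering, shares were 6.665% smooth muscle-like and 8.834% KRT19-led, the G2 and M median of mesenchymal-like cells was 0.6013 and the integrin median of smooth muscle-like cells 0.513, and the haem median of blood sub-cluster 5 turned to −0.01915. With at least 2 UMIs demanded, RUNX1 was found in 0% of endothelial-like and 6.667% of blood-like cells, and with 2500 UMIs per cell in 17.65% of blood-like cells. The demand for 2 UMIs lowers detection by construction. Each share in a draw comes from 1 random draw, and the expected endothelial-like share of 0.742% was 0.889% with at least 1500 genes and 0.776% with doublet calls kept in.

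With all list members kept, genes near 0 CPM enter and the pseudocount draws medians to 0 by construction. Against endothelial-like cells, values were −0.5991 (VEGF) in blood-like cells, −0.5772 (VEGF) and 0.465 (G2 and M) in mesenchymal-like cells, and −0.9955 (blood stem cell programme) and 0.06692 (integrins) in smooth muscle-like cells. In arterial-like cells they were 0.0893 (Notch) and −1.112 (G2 and M). Medians that turned were −0.0141 (WNT) and −0.01032 (retinoic acid) in arterial-like cells, 0.01925 (WNT), 0.006058 (blood stem cell programme) and 0.03601 (heat shock) in blood-like cells, 0.01017 (Notch) and −0.00197 (retinoic acid) in mesenchymal-like cells, −0.02397 (retinoic acid) in smooth muscle-like cells and −0.01532 (haem) in blood sub-cluster 5. With a pseudocount of 1 CPM, which widens ratios by construction, medians were −2.074 (G2 and M) in arterial-like cells, −2.76 (VEGF) and 0.9607 (haem) in blood-like cells, −1.992 (VEGF) and 0.614 (G2 and M) in mesenchymal-like cells, and −2.867 (blood stem cell programme) and 0.8081 (integrins) in smooth muscle-like cells.

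With a mean of CPM over cells, medians were −1.437 (G2 and M) in arterial-like cells, −2.623 (VEGF) and 0.8631 (haem) in blood-like cells and 0.5885 (G2 and M) in mesenchymal-like cells. In blood-like cells COL18A1 (−0.08123), MALAT1 (−0.1191), RRM1 (0.01701), RRM2 (0.04342) and TYMS (0.1504) turned, and in smooth muscle-like cells the retinoic acid median (−0.4587). With median-of-ratios scaling, blood-like cells had −2.295 (VEGF) and 0.8851 (haem). The G2 and M median of arterial-like cells was −0.4331 against the venous-marker sub-cluster alone, −1.678 without endothelial sub-cluster 4 and −0.2029 without the cycling sub-cluster. Counting cluster 2 as mesenchymal-like gave a G2 and M median of 0.3997 there.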

Other observations

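Of the 4 tests in this part, all were chosen only after the values they measure had been seen; the comparison of smooth muscle-like with mesenchymal-like cells and the second clustering of blood-like cells were also chosen after the data were seen.

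HOX genes of the A and B clusters differed in level at day 6. The 11 HOXA genes summed to 0.914 CPM in endothelial-like cells, 0.410 CPM in blood-like cells and 5.67 CPM in mesenchymal-like cells. The 9 HOXB genes summed to 262 CPM, 113 CPM and 375 CPM in the same classes, with HOXB6 at 64.2 CPM in endothelial-like cells. PTPRC, which encodes the pan-leukocyte antigen CD45, had 0 UMIs in the 511 blood-like cells, which allows a level of up to 0.252 CPM by the exact Poisson bound. In the same cells SPI1, a transcription factor of early blood cells, stood at 118 CPM.

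Among the gene lists, which leave out the markers that define the classes, smooth muscle-like cells differed most from mesenchymal-like cells in genes of division. The G2 and M list had a median log2 ratio of −1.32, with 25 of 37 members at least 2-fold lower, and the S phase list −0.89, with 4 of 20 lower. UBE2C stood at 17.1 against 195 CPM, TOP2A at 4.53 against 66.9 CPM and MKI67 at 7.53 against 57.6 CPM. Integrins and adhesion genes had a median of 0.39, cholesterol synthesis 0.31, glycolysis 0.27, heat shock genes 0.26 and the BMP and TGF-beta list 0.22. Medians were lower for the blood stem cell programme (−0.44), the HOXB cluster (−0.31) and the matrix list (−0.17), and at most 1 member of each of these 8 lists passed 2-fold. IL32 was 4.46-fold higher (4.09 to 4.86), TNFRSF12A 2.496-fold and CCL2 8.14-fold. The mesenchymal-like class includes clusters led by cell cycle genes, and how much of the difference follows from how the classes were drawn was not tested.

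RUNX1 and endothelial genes were both abundant in blood sub-cluster 5, a group of 54 barcodes. Free RNA from blood cells is argued against by HBG2, the most abundant blood transcript, which was 0.4487 times the arterial-like level (0.29 to 0.62) while RUNX1 was 44.5 times that level. Free RNA from endothelial cells stays open, because 3 forms of the test, all set after the data were seen, gave different answers. The UMIs per droplet of 7 endothelial genes were 0.8593 times (0.681 to 1.06) those of the same top fraction of mesenchymal-like and smooth muscle-like droplets, and 3.142 times (2.25 to 4.28) without RAMP2 and PLVAP, which were left out only after the first value had been seen. In those 2 classes RAMP2 and PLVAP stood at 189 and 187 CPM, against 29.8 and 142 CPM in other blood-like cells. The median share of the endothelial level over 13 genes kept out of the clustering was 1.27 times the lowest share the 7 genes needed. By single gene the share ran from 1.52% (ESM1) to 56.3% (IFI16) among the 13. Among the 7 it ran from 18.7% (CLDN5) to 71.7% (PECAM1). With single endothelial sub-clusters other than 0 as the source, and 9 to 23 genes, the ratio ran from 0.63 to 3.23. Sub-cluster 0 gave no usable ratio, because its lowest share came out negative (−728%). Droplets with 1 endothelial and 1 blood cell stay open too. SPI1, SPN and GFI1B lay lower against progenitor sub-cluster 3 than RUNX1 did, by a median of −1.304 on the log2 scale. The interval of −1.83 to −0.81, however, crossed the bound of −1. The median UMI total of sub-cluster 5 was 24545, 1.22 times that of arterial-like cells but below the 31905 of sub-cluster 3. Its median doublet score of 0.0357 was above those of arterial-like cells (0.0317) and sub-cluster 3 (0.0156).

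Day 0 barcodes overlapped little with those of the later days. Days 2, 4 and 6 shared 459, 243 and 61 barcodes pair by pair, from which a list of 778639 possible barcodes follows. Day 0 shared 18 barcodes with the other days (10.7 to 28.4) where 798 would follow from a list of that size. Without day 2, whose list of 37586 barcodes is far longer than the others, it shared 2 with day 4 and 3 with day 6, where 139.8 and 82.4 would follow. The value of 18 argues against day 0 drawing on the same barcode list as days 2, 4 and 6, and a candidate explanation is that the day 0 library was made with a kit of another barcode list, although the labels give the same chemistry for all 4 libraries.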
